A study of Homo sapiens with 10 samples.

How the data were processed

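The series holds 10 samples of U2OS cells, 5 DRIP libraries and 5 input samples. Per the labels' protocols, nucleic acids of nuclei that were not crosslinked were sonicated, RNA-DNA hybrids were pulled down with the S9.6 antibody, the immunoprecipitated samples were treated with RNase H before second strand synthesis, and libraries were made with an NEBNext Ultra II kit and sequenced on an AVITI instrument. The labels also state that the antibody lots differed between the experiments. The sources used here hold no processed files of the input samples, which are not analysed here.

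The submitters' processing notes list FastQC 0.11.5, BWA 0.7.17-r1188, SAMtools 1.9, deepTools 3.5.1 and MACS3 3.0.0a6, and hg38 as the build, without their roles or order. Each DRIP library has 1 deposited peak list in the narrowPeak layout, and the control and options used for calling are not given in the sources used here. The deposited score of a peak equals 10 times its deposited -log10 q, rounded down to a whole number, in 99.974% to 99.995% of the peaks of each list. Per the layout of the deposited files, the other values are the fold enrichment of the peak, a ratio over the caller's background estimate, its -log10 p and its -log10 q. The lowest deposited -log10 q was just above 2 in each list (2.00 to 2.01). The lists hold peaks on chromosomes 1 to 22 and X only, so the 15 genes of the mitochondrial genome list are not analysed here. Read depth, read counts and input signal are not given in the sources used here, so no depth or counting interval per region could be computed.

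The gene table used is RefSeq on GRCh38.p14 with 59098 genes, of which 19974 are protein-coding. It gives the start and end of each gene without strand or exons. The planned classes of promoters, transcript ends, exons and introns were therefore replaced by gene ends (within 1 kb of either end of a protein-coding gene), gene interiors, other genes and intergenic sequence, and the planned promoter windows by windows of 1 kb around both gene ends. Coordinates are 1-based.

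From the lists were computed the number of peaks and covered bases per library, the Jaccard index of covered bases for each pair of libraries with 100 random placements of the peaks on their chromosomes, the share of peak bases in each annotation class, and merged regions with the libraries that have a peak in each. The share in a class was compared between 3 SCAN1 and 2 WT libraries with an exact two-sided permutation test over 10 splits. For each gene, extended by 1 kb at both ends, the percent covered by peaks was computed from the 63456 peaks of highest -log10 p in each library, the length of the shortest list. Protein-coding genes with a mean of at least 2% over the 5 libraries were tested with limma 3.58.1 (lmFit, eBayes with trend; Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3, with both SCAN1 lines as one group. Gene lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01 and again with an estimated one, adjusted over the lists. The share of peak bases in bins of 5 Mb, with 500 bases added to each value, was set against WT of the same experiment, and blocks are adjacent bins beyond 0.3 on the log2 scale in the same direction in all 3 comparisons, among bins with at least 10 peaks on average. Differences between the SCAN1 lines are values with no test. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

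There were 17 gene lists, fixed before the data were examined, as were the groups, tests and named-gene rule: TOP1 and strand-break repair, R-loop processing, hereditary ataxia, cytosolic ribosomal proteins, replication-dependent histones, immediate early response, very long and fragile-site genes, synaptic and neuronal, silent lineage markers, osteoblast and mesenchymal, p53 targets, DRIP positive and negative control loci, RNA polymerase III and snRNA genes, the mitochondrial genome, olfactory receptors and ZNF genes. The rule names, per direction, up to 12 protein-coding genes past an adjusted p of 0.05 by the size of their difference, filled where fewer pass with the genes whose smallest difference over the 3 comparisons within experiments was largest, all of the same sign. It also names TDP1, 2 to 4 members of each described list with the largest differences or highest coverage, and the 5 peaks of highest fold enrichment in each library. Genes called on the log2 scale, genes of distal chromosome 14, members of the chromosome blocks, the lower members of the p53 list, negative control loci, OR5C1 and genes that differed between the SCAN1 lines were chosen after their values were seen. Some genes that the rule names are not reported here.

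The labels give the replicate number as the number of the experiment, so the numbers pair the samples. The deviations from the group means correlated across genes by 0.612 for WT and SCAN1#1 in experiment 1, 0.325 for WT and SCAN1#1 in experiment 2 and 0.470 for WT and SCAN1#2. The fit without the block was fixed as the primary one, with the block as an alternative.

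The gene test was tested on simulated data with the spread of the real libraries, 200 of 8472 genes being shifted. Shifts of 10, 20 and 40 points were recovered for 16%, 43.5% and 63% of shifted genes, with 1, 5 and 15 false calls and 0 in the wrong direction. Random lists of genes with no shift fell under 0.05 with camera in 1.5% to 6% of draws. Genes drawn at random do not carry the correlation between members of a real list. The draws therefore do not check the preset correlation. For the p53 targets the correlation estimated from the real libraries was 0.0907, and 0.00643 with experiment as a block. Alternatives were a -log10 q of at least 5, lists as deposited or of equal length, windows of 2 kb, summits, merging within 1 kb, regions covered over 50%, log2 of the percent plus 1, quantile normalization, no coverage filter, the median of each 5 Mb bin taken out, bins of 10 Mb, the experiment as a block, the SCAN1#1 line alone, experiment 2 alone, and leaving out each library in turn.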

Results

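DRIP-seq, in which the S9.6 antibody pulls down RNA-DNA hybrids (R-loops) from sonicated nucleic acids for sequencing, was carried out in U2OS osteosarcoma cells. Per the labels, the cells were either wild type (WT) or carried TDP1 H493R, the change behind SCAN1, spinocerebellar ataxia with axonal neuropathy. TDP1 is an enzyme that removes trapped topoisomerase 1 from DNA ends, and the series asks how the mutation bears on DNA breaks that arise during transcription. Peak lists exist for 5 DRIP libraries: WT in experiments 1 and 2, the line SCAN1#1 in experiments 1 and 2, and the line SCAN1#2 in experiment 2. The replicate number of each library is its experiment. Read depth is not given in the sources used here. The limma and permutation p-values below measure only the spread between samples. The labels do not say whether replicates were separate cultures. The p-values of camera with the preset correlation set the genes of a list against the other tested genes. They are not a measure of the spread between samples. With SCAN1#1 giving 2 of the 3 SCAN1 libraries, none of these p-values measures the spread between lines of a genotype.

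Peaks numbered 82545 and 89445 in WT replicates 1 and 2, 63456 and 110745 in SCAN1#1 replicates 1 and 2, and 89932 in SCAN1#2 replicate 2. They covered 49.2, 55.4, 41.4, 66.8 and 51.4 Mb of chromosomes 1 to 22 and X in the same order. Against WT of the same experiment, the log2 ratio of covered bases was -0.25 for SCAN1#1 in experiment 1, 0.27 for SCAN1#1 in experiment 2 and -0.11 for SCAN1#2 in experiment 2. The median peak was 371 to 430 bases wide, with a median fold enrichment of 4.84 to 5.94. With 1 library of each line per experiment these ratios have no replicate check within an experiment.

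The strongest peaks lay over the same few loci in both genotypes. Peaks at the histone genes H1-4 and H2BC5 on chromosome 6 (26155402 to 26162947, GRCh38) reached fold enrichments of 165 to 262 and were among the 5 strongest of 4 libraries. The linker histone gene H1-2 (26052687 to 26057004) reached 192 to 254 in 3 libraries, and RPS12, which encodes a protein of the small ribosomal subunit, 117 to 188 in 3 libraries. A peak over TNFRSF12A, HCFC1R1 and THOC6 reached 126 in WT replicate 2. The long noncoding RNA gene LOC101930665 on chromosome 17 was among the strongest in 4 libraries by itself (125 to 219) and together with LOC100533653 in WT replicate 1 (229). LOC105371703, also on chromosome 17, reached 192 and 206 in 2 libraries and 180 with TUFMP1 in WT replicate 1. A stretch of chromosome 21 with no annotated gene (9527182 to 9537263) reached 149 to 273 in 5 libraries. Each of these peaks was overlapped by a peak in all 5 libraries.

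Gene groups fixed before the data were examined differed widely in how much of their length lay under peaks. With lists of equal length (the 63456 strongest peaks of each library), the 78 cytosolic ribosomal protein genes were covered over 58.8% to 66.3% of their length on average, and 97.4% to 100% of them had a peak. RPS21 and RPL8 were covered over 100% in every library. The 10 loci often used as DRIP positive controls averaged 41.9% to 59.3%, with ACTB at 100% in every library, and the 6 negative control loci 1.82% to 3.29%. HBB, MYOD1 and TSHB among the latter had no peak in any library, whereas ZNF544 was covered over 10.2% to 19.4%. Immediate early genes averaged 32.2% to 41.5% and replication-dependent histone genes 20.4% to 34.4%. The 26 RNA polymerase III and snRNA genes averaged 9.25% to 19.2%, and RNU11, RNU4-2 and RNU1-2 had the highest mean coverage among them. Olfactory receptors (0.22% to 0.68%), very long and fragile-site genes (0.188% to 0.516%) and markers of unrelated lineages (1.07% to 3.16%) were at the low end. The low percentages of the very long genes go with their length, since 85.7% to 92.9% of them had a peak, against 3.33% to 9.23% of the olfactory receptors. Over all protein-coding genes, 13% to 17% of the length was covered in those under 10 kb and 0.527% to 0.937% in those of 200 kb and longer, while 40.4% to 44.1% of the former and 79.6% to 92.8% of the latter had a peak.

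**Figure D1:**
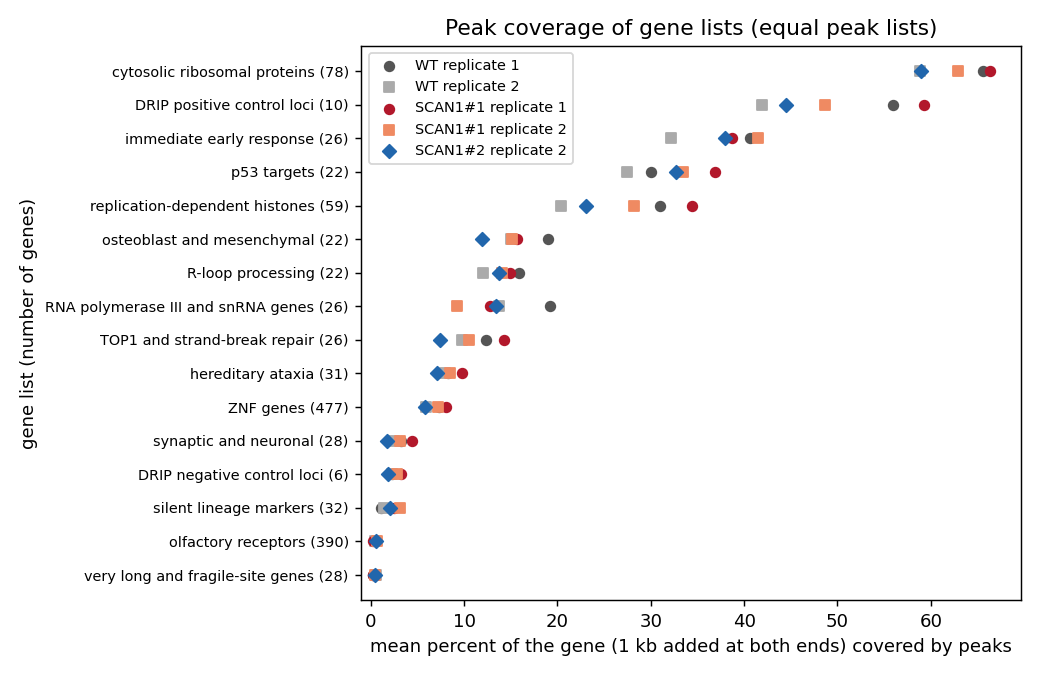
Mean percent of each gene covered by peaks (x axis) for 16 gene lists (y axis, number of genes in parentheses), one point per library, from peak lists of equal length. Ribosomal protein genes sit at 58.8% to 66.3% and olfactory receptors at 0.22% to 0.68% in the 5 libraries.

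Whether libraries resembled each other by genotype or by experiment was asked from the bases that their peaks share. By covered bases, libraries of the same experiment overlapped more than libraries of different experiments. The Jaccard index averaged 0.419 (0.390 to 0.436) over the 4 pairs from the same experiment and 0.340 (0.316 to 0.363) over the 6 pairs from different experiments. The SCAN1 lines of experiment 2 shared 0.430 and WT and SCAN1#1 of the same experiment 0.436, while the WT libraries of the 2 experiments shared 0.357. Peaks moved to random places on their chromosomes gave about 0.0127 for the WT and SCAN1#1 libraries of experiment 1. The ranges of the 4 and the 6 pairs did not touch for this measure, and no p-value was computed because pairs share libraries. By the percent of peaks with a reciprocal overlap of 50% they did, at 33.0 to 50.1 and 30.2 to 37.45, with WT and SCAN1#1 of experiment 1 at the low end of the former.

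**Figure D2:**
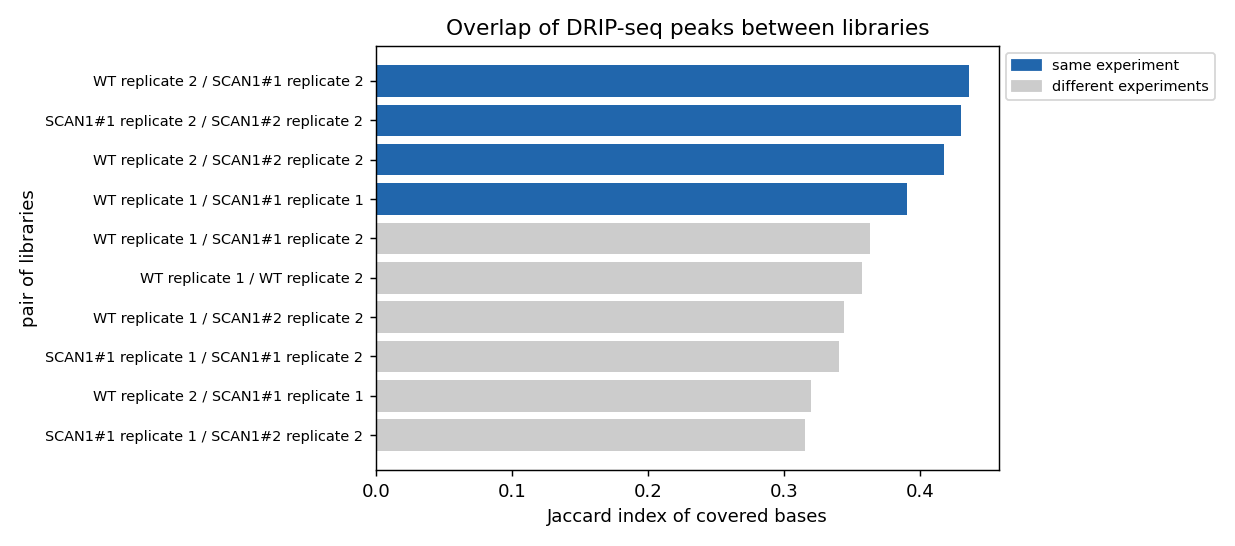
Jaccard index of covered bases (x axis) for each of the 10 pairs of libraries (y axis), coloured by whether both come from the same experiment. The 4 pairs of the same experiment lie at 0.390 to 0.436, above the 6 others at 0.316 to 0.363.

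Peaks were concentrated at the ends of protein-coding genes in both genotypes. Sequence within 1 kb of either end of a protein-coding gene makes up 2.39% of the genome and held 16.2% ± 3.13 (SD, n = 3) of peak bases in SCAN1 libraries and 15.2% ± 2.87 (SD, n = 2) in WT libraries. Gene interiors held 52.6% ± 3.70 and 52.5% ± 2.45, other genes 7.98% ± 1.34 and 7.98% ± 1.23, and intergenic sequence 23.2% ± 5.06 and 24.3% ± 4.09. The difference at gene ends, 1.01 percentage points, was smaller than the spread between libraries (exact two-sided permutation test, p = 0.8, where the 10 splits of 5 libraries allow no p below 0.1). Within experiments the share at gene ends was higher by 2.48 points in SCAN1#1 of experiment 1, by 0.54 in SCAN1#1 of experiment 2 and by 2.03 in SCAN1#2, and the mean of the differences with experiment as a block was 1.88 points. Leaving out WT replicate 2 turned the pooled difference to -1.02 and leaving out SCAN1#1 replicate 1 to -0.745.

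Few regions had a peak in every library of one genotype and in none of the other. Of 177004 merged regions, 21944 had a peak in all 5 libraries and 76285 in 1 library. A peak in all 3 SCAN1 libraries and in no WT library was found in 1673 regions, and a peak in both WT libraries and in no SCAN1 library in 2466. Of the 2466 regions, 62 (2.51%) lay on chromosome 14 between the start of TDP1 and the chromosome end, against 0.308% of all regions and 0 of the 1673. Gene ends made up 4.96% of the 2466 regions, 12.2% of the 1673 and 11.9% of all regions, with median widths of 433, 602 and 424 bases. A peak in 3 libraries and a peak in 2 are unlike conditions, and these shares are not given for other splits. Their contrast therefore does not measure a difference of genotype. Among the 10 ways to part the 5 libraries into 3 and 2, the real one ranked 6 for either count, and the split by experiment gave 9341 regions present in all 3 libraries of experiment 2 alone and 2883 in both of experiment 1 alone (5764 and 4815 with lists of equal length). Both counts rested on which libraries were used: leaving out 1 library gave 2743 to 9297 and 3388 to 17667 regions.

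The next comparison asks which protein-coding genes gained or lost peak coverage in SCAN1 cells. No gene passed the threshold among 8472 tested (limma, 0 higher and 0 lower, smallest adjusted p = 0.358), while 164 were higher and 131 lower at an unadjusted p under 0.05. With experiment as a block limma again called 0 and 0, with 298 and 220 at an unadjusted p under 0.05. On a log2 scale limma called 3 genes higher, LOC124900418, GDF15 (a stress-induced cytokine) and PNRC1, and 1 lower, BEX4. That fit used lists of equal length, where PNRC1 was at 0% in both WT and BEX4 at 0% in all 3 SCAN1 libraries. Such a group has no spread between its libraries, and as deposited neither group was at 0% throughout. Since no gene passed on the percent scale, the genes named here are those whose smallest difference over the 3 comparisons within experiments was largest. Their sign was the same in all 3, and none of them is past the threshold on the percent scale.

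On the higher side, DEPP1 on chromosome 10 (44976128 to 44978809), a regulator of autophagy, was covered over 49.97% ± 6.46 (SD, n = 3) in SCAN1 and 5.05% ± 7.14 (SD, n = 2) in WT libraries. PNRC1, a nuclear receptor coactivator gene on chromosome 6 (89080751 to 89085160), had no peak in either WT library with lists of equal length and was covered over 22.7%, 22.9% and 32.3% in the SCAN1 libraries. In the lists as deposited PNRC1 was covered over 3.81% and 15.3% in WT and 22.7%, 29.2% and 32.3% in SCAN1 libraries. LAMB3, which encodes a laminin chain, was covered over 40.1% ± 7.54 against 8.64% ± 2.62, and FBXW5 over 66.7% ± 9.05 against 37.1% ± 3.79. NAT14 differed by 43.6 points, and it lies in a part of chromosome 19 (55000001 to 58599484) in which the share of peak bases was higher in all 3 SCAN1 libraries. OVCA2 differed by 53 points, and it lies in the first 10 Mb of chromosome 17, where the SCAN1#1 libraries had 905 and 1013 peaks, SCAN1#2 538 and the WT libraries 764 and 530. In the lists as deposited OVCA2 was covered over 30.8% and 51.2% in WT and 74.2%, 98.8% and 59.6% in SCAN1 libraries. The others were COA3 (32.0 points), SYTL1 (32.0), NEURL2 (24.7), the histone gene H4C5 (35.9), PHLDA2 (32.7) and ARFRP1 (23.6).

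On the lower side, XRCC3, a homologous recombination gene on distal chromosome 14 (103697617 to 103715451), was covered over 11.1% ± 14.2 in SCAN1 and 62.2% ± 22.9 in WT libraries. COL1A1, the type I collagen gene, was covered over 23.8% ± 13.6 against 61.2% ± 7.65, and THY1, a surface marker of mesenchymal cells, over 18.8% ± 1.55 against 47.6% ± 4.91. At gene ends only, most of the difference of COL1A1 was gone, as were most of those of FOXM1, ZNHIT1, LOXL4 and TEAD3 named below. THY1 was below the coverage filter at gene ends and was not tested there. BEX4 on the X chromosome had no peak in any SCAN1 library with lists of equal length and was covered over 27.0% and 23% in the WT libraries (limma, adjusted p = 0.358). In the lists as deposited the SCAN1 libraries covered BEX4 over 0%, 18.7% and 6.47%. CIRBP, a cold-inducible RNA-binding protein gene, differed by -26.8 points, FOXM1, a cell cycle transcription factor gene, by -29.8, and the metallothionein gene MT1E by -25.2. TEAD3 (-26.8) lies in a 5 Mb bin of chromosome 6 with a lower share of peak bases in the SCAN1 libraries. The remaining genes were SNAPC5 (-32.2), ZNHIT1 (-27.0), LOXL4 (-27.4) and TMEM147 (-31.6). Without WT replicate 2 or 1 the difference was -49.2 or -14.1 for TMEM147 and -45.6 or -14.0 for FOXM1. In the same order, ZNHIT1 was at -38.8 or -15.2 and SNAPC5 at -43.9 or -20.6. TDP1 itself was below the coverage filter, with 2 peaks in each of 4 libraries and 0 in SCAN1#2, which does not check a label of a point mutation. All 3 differences were positive in 19.3% of tested genes and negative in 15.8%, where simulated libraries with no effect and the same shared WT library gave 16.5% and 16.6%. The simulated libraries had no offset between them, whereas the real differences averaged 0.51, 2.26 and -0.615 points over tested genes. An excess of genes with 1 sign can therefore not be read from these shares. Peaks carry no strand, so neighbouring or overlapping genes can share a peak.

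**Figure D3:**
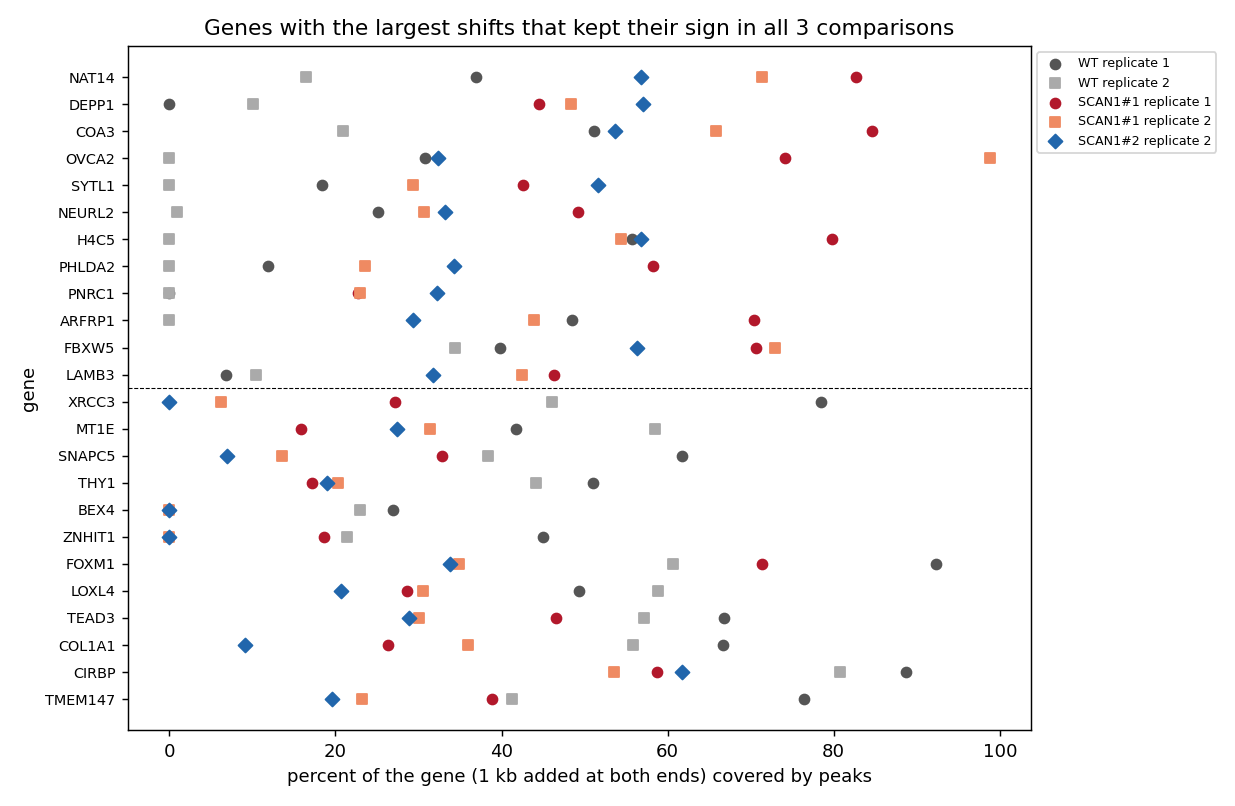
Percent of each named gene covered by peaks (x axis) in the 5 libraries, one point per library, for the 12 higher (above the dashed line) and 12 lower genes (below it) on the y axis. With lists of equal length, BEX4 is at 0% in the 3 SCAN1 libraries and at 23% and 27.0% in WT, and PNRC1 at 0% in both WT libraries.

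Of the gene lists fixed beforehand, the targets of p53, the stress-response transcription factor, had higher coverage as a group in SCAN1 libraries in camera with the preset correlation. Of the 18 tested members, 16 were higher and 2 lower, with a mean difference of 6.92 points (camera, adjusted p = 8.31e-06 over 13 lists). That call was lost in camera with an estimated correlation (adjusted p = 0.559, correlation 0.0907). With experiment as a block it was lost as well (camera, adjusted p = 0.453), though the estimated correlation of 0.00643 was below the preset 0.01. The size of the correlation alone therefore does not account for the loss. The mean coverage of the 18 genes was 36.5% and 33.2% in WT replicates 1 and 2, 45.0% and 40.7% in SCAN1#1 replicates 1 and 2, and 39.7% in SCAN1#2 replicate 2. Within experiments the mean difference was 8.46 points for SCAN1#1 in experiment 1, 7.47 for SCAN1#1 in experiment 2 and 6.50 for SCAN1#2, with 15, 15 and 16 of the 18 higher, and over all tested genes it was 0.51, 2.26 and -0.615. FDXR, a mitochondrial electron carrier enzyme gene, was covered over 28.4% and 25.2% in WT and 71.5%, 68.9% and 37.1% in SCAN1 libraries. CDKN1A, which encodes the cell cycle inhibitor p21, was covered over 23.3% and 24.1% in WT and 55.0%, 25.4% and 48.0% in SCAN1 libraries. BBC3, the gene of the apoptosis inducer PUMA, differed by 17.1 points and TIGAR by 11, whereas PHLDA3 (-1.04) and BAX (-0.58) were the 2 lower members. Of the list, 0 genes passed over all genes tested and 0 adjusted over the list alone, with 2 at an unadjusted p under 0.05. With coverage counted at gene ends only the mean difference was 6.51 and the list was no longer called (adjusted p = 0.189).

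**Figure D4:**
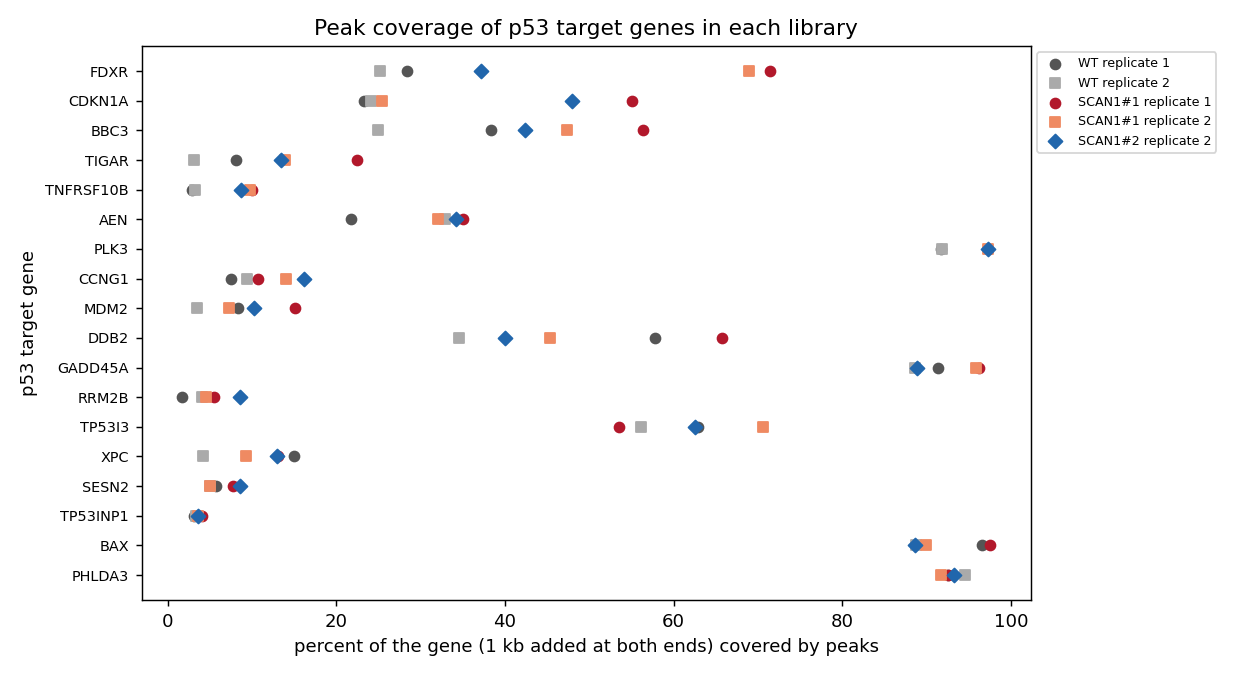
Percent of each of the 18 tested p53 target genes covered by peaks (x axis), one point per library, with genes ordered by the difference of SCAN1 from WT on the y axis. FDXR stands at 28.4% and 25.2% in WT and at 37.1% to 71.5% in SCAN1 libraries, and PHLDA3 and BAX at the bottom were lower in SCAN1.

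Replication-dependent histone genes were higher in 25 and lower in 13 of 38 tested members, by 4.32 points on average, which did not pass (camera, adjusted p = 0.285). H4C5 (35.9 points), H2BC14 (24.3) and H2AC20 (17.5) had the largest positive differences and H3C2 (-16.6) the largest negative one. The result rested on single libraries: the mean was 12.7 points without WT replicate 1 (adjusted p = 0.00033), 8.85 without SCAN1#2 replicate 2 (adjusted p = 0.0246), -3.76 without WT replicate 2 and -0.0927 without SCAN1#1 replicate 1. These histone adjusted p-values are from camera with the preset correlation. The osteoblast and mesenchymal list averaged -4.71 points over 12 tested members, 6 higher and 6 lower (adjusted p = 0.505), with COL1A1 and THY1 at the low end and TGFBI, an extracellular matrix gene, 12.4 points higher, and the mean ran from -9.28 without WT replicate 2 to -0.942 without WT replicate 1. Immediate early genes averaged 3.41 points over 22 members (adjusted p = 0.578), led by IER2 (26.9) and BTG2 (26.8), and the mean was -1.55 without WT replicate 2 and 8.37 without WT replicate 1.

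Lists of genes that act on the lesions or structures under study were not called. The TOP1 and strand-break repair list averaged -0.57 points over 16 tested members (adjusted p = 0.89), with LIG3, a DNA ligase gene, at 10.6 and FEN1, a flap endonuclease gene, at -9.28. R-loop processing genes averaged -0.13 points over 13 members while camera's direction was up (adjusted p = 0.822), with the helicase genes DDX21 at -7.17 and DDX5 at 6.61. Hereditary ataxia genes averaged 0.72 points over 13 members (adjusted p = 0.822), with AFG3L2 at 8.69 and APTX, the gene of another ataxia with a DNA end-processing defect, at -5.58. Leaving out 1 library turned the sign of all 3 means, over -3.48 (without SCAN1#1 replicate 1) to 2.16 (without SCAN1#2 replicate 2) for repair, -3.21 (without WT replicate 2) to 3.10 (without WT replicate 1) for R-loop processing and -1.03 (without SCAN1#1 replicate 1) to 2.40 (without SCAN1#2 replicate 2) for ataxia. In limma, 0 members of these 3 lists passed over all genes tested and 0 adjusted over the list alone. At an unadjusted p under 0.05 there were 1, 1 and 2 genes in the 3 lists, APTX among them.

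The other lists were not called in the main fit either. Cytosolic ribosomal protein genes averaged 0.49 points over 78 genes, 42 higher and 36 lower (adjusted p = 0.578), with RPS15 at -30.2 and RPL7 at 22.4. ZNF genes averaged 0.79 points over 236 genes (adjusted p = 0.397), with ZNF628 at 26.1 and ZNF3 at -19.7. DRIP positive control loci averaged 3.21 points over 7 genes (adjusted p = 0.514), with BTBD19 at 23. Markers of unrelated lineages averaged 5.34 points over 7 genes (adjusted p = 0.578), mainly from the alpha-globin gene HBA1 at 38.4. Synaptic and neuronal genes averaged 0.33 points over 9 genes with a median of -0.51 and a downward camera direction (adjusted p = 0.514). Olfactory receptors averaged 1.04 points over 27 genes with a median of -0.48 and a downward camera direction (adjusted p = 0.651). One olfactory receptor, OR5C1, passed when adjusted over the list alone (covered over 7.96% and 9.55% in WT and 0% in all 3 SCAN1 libraries with lists of equal length, but 12.7% in SCAN1#1 replicate 2 as deposited), and 0 passed over all genes tested. No list was called with an estimated correlation.

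Along the chromosomes, the end of chromosome 14 stood out. From the start of TDP1 to the chromosome end (89954968 to 106879844, 16.9 Mb), WT libraries had 360 and 327 peaks and SCAN1 libraries 69, 113 and 84. These were 0.436% (95% Wilson interval 0.393 to 0.483) and 0.366% (0.328 to 0.407) of all peaks in WT replicates 1 and 2. In SCAN1#1 replicates 1 and 2 and in SCAN1#2 replicate 2 they were 0.109% (0.0859 to 0.138), 0.102% (0.0849 to 0.123) and 0.0934% (0.0755 to 0.116). The rest of chromosome 14 held 2.87% to 3.06% of peaks in every library. The log2 ratio of the share of peak bases in the block from 90000001 to the end was -2.11 and -1.85 for SCAN1#1 and -2.04 for SCAN1#2. Of 24 tested genes there, 23 were lower in SCAN1, against 49.0% of 263 genes on the rest of the chromosome. Besides XRCC3 they include TRMT61A (-19.0 points), the apoptosis modulator gene MOAP1 (-16.3) and INF2 (-15.0). As deposited, MOAP1 was covered over 13.6% and 18.9% in WT, 0% in both SCAN1#1 libraries and 17.6% in SCAN1#2. PLD4 (1.97) was higher, and 16 of the 24 genes were lower in all 3 comparisons within experiments. Intervals cover counting error of peaks only.

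**Figure D5:**
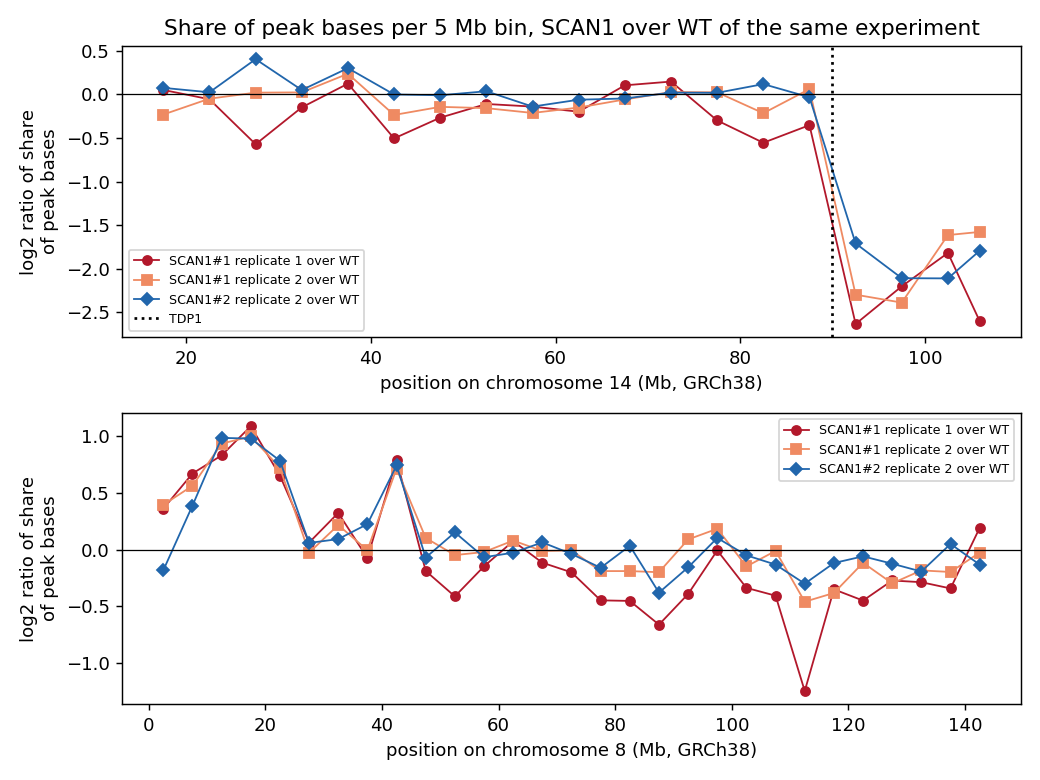
Log2 ratio of the share of peak bases in 5 Mb bins (y axis), each SCAN1 library over WT of the same experiment, along chromosomes 14 and 8 (x axes in Mb, GRCh38), with a dotted line at TDP1. The 3 lines drop together past TDP1, to block values of -2.11, -1.85 and -2.04, and lie above 0 in the block from 5000001 to 25000000 of chromosome 8.

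Smaller blocks differed in the same direction in all 3 SCAN1 libraries. The short arm of chromosome 8 from 5000001 to 25000000 had log2 ratios of 0.73, 0.78 and 0.79, and the bin from 40000001 to 45000000 0.80, 0.72 and 0.75. The p53 target TNFRSF10B, a death receptor gene, lies in the former block and was covered over 2.87% and 3.26% in WT and 9.96%, 9.77% and 8.71% in SCAN1 libraries. On chromosome 4, the blocks from 140000001 to 155000000 (0.63, 0.48, 0.56) and from 180000001 to 190000000 (0.40, 0.57, 0.60) were higher. On chromosome 10, the blocks from 85000001 to 95000000 (-0.83, -0.45, -0.61) and from 115000001 to 125000000 (-1.07, -0.40, -0.43) were lower, as was the bin of chromosome 6 from 35000001 to 40000000 (-0.57, -0.31, -0.44). In all, 23 of 578 bins were higher and 10 lower by more than 0.3 in each comparison. Parting the libraries within experiments with SCAN1#1 set apart in both gave 21 and 8 bins, and the other 4 arrangements at most 6 and 9. With SCAN1#1 set apart, higher means above SCAN1#1, and in experiment 1 this is the real comparison with its sign turned. Across bins, which are not independent replicates, the log2 ratios of SCAN1#1 in experiments 1 and 2, which share no library, correlated with r = 0.662, and those of SCAN1#1 in experiment 1 and SCAN1#2 with r = 0.386 and the same sign in 49.8% of bins. Across 8472 genes the differences of the same pairs of comparisons correlated with r = 0.254 and r = 0.062.

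The SCAN1 lines could be compared with each other in experiment 2, with 1 library each and so without a test. Of the 40 genes with the largest differences, 35 were covered more in SCAN1#1 and 5 more in SCAN1#2. Lists of equal length still covered 46.5 Mb in SCAN1#1 and 40.7 Mb in SCAN1#2, an offset that was not taken out. Of the 5, CATSPERH (0% against 54.55%) went the other way as deposited (79.8% against 54.55%). With lists of equal length ACTL10 was covered over 82.9% in SCAN1#1 and 0% in SCAN1#2, and 5 of the 40 genes lie close together on chromosome 14 (24136194 to 24312038), among them PSME1 (58.9% against 0%, and 64.4% against 35.0% as deposited), a proteasome activator gene, and LTB4R2 (83.7% against 14.7%). AURKAIP1 (0% against 64.7%, though 44.5% in SCAN1#1 replicate 1 and 26.9% against 70.0% as deposited) lies in the first 5 Mb of chromosome 1, where SCAN1#1 had 200 peaks and SCAN1#2 319. Over the first 10 Mb of chromosome 17, with SENP3, KCTD11 and DVL2, SCAN1#1 had 1013 peaks and SCAN1#2 538, against 530 in WT replicate 2. Chromosome 15 from 45000001 to 55000000 had 140 and 233 peaks. The SD of the differences over 8472 genes was 8.98 points between the lines, 8.40 for SCAN1#1 against WT and 8.37 for SCAN1#2 against WT. The SCAN1#2 list had fewer peaks than that of SCAN1#1, and with lists of equal length the mean difference over genes was -2.87 points, with 67 genes over 20 points higher and 409 lower in SCAN1#2.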

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

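The tests of where chromosome 14 splits, of list length and of other arrangements for the share at gene ends, and the mean difference of the p53 targets under each alternative, were chosen only after those results were seen.

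The covered genome of SCAN1#1 relative to WT went opposite ways in the experiments, with a log2 ratio of -0.25 in experiment 1 and 0.27 in experiment 2, and this difference was not tested since each experiment has 1 library of each line.

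The 3 SCAN1 libraries had 0.0934% to 0.109% of their peaks on chromosome 14 beyond TDP1, against 0.366% and 0.436% in WT. A lower transcription confined to the span of protein-coding genes there is argued against by the peaks outside these genes. Their ratio to WT was 0.142 (95% interval 0.0768 to 0.265), 0.268 (0.192 to 0.376) and 0.267 (0.186 to 0.384), against 0.288, 0.286 and 0.246 inside them. A lower transcription of the whole segment would lower both kinds of peaks and stays open. A loss of DNA copies from TDP1 to the chromosome end stays open: the position that best splits the chromosome lay 221, 376 and 376 kb from TDP1, but the 5 Mb bins that raised the pattern had already placed the step there, so this distance decides nothing. The input samples, not analysed here, would bear on copy number directly. An effect of the TDP1 genotype on hybrids along this segment stays open as untested.

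The p53 targets were covered more in SCAN1 libraries by 6.92 points. A shift of genes at that coverage level is argued against by a rank at the percentile 99.99 of 10000 matched lists. A single library as the whole cause is argued against by means of 5.04 to 8.17 points when each library was left out. After the median of each 5 Mb bin was taken out the mean difference was 6.70. That step also left XRCC3, on distal chromosome 14, at -45.4 against -51.1 before. It thus takes out little of a regional shift, and regional shifts such as copy number stay open. Of the 10 splits of the libraries into 3 and 2, the real one alone (1 split) gave a difference as large in size, 6.92 against at most 6.35 in the others, and 10 splits are too few for a share under 0.05. The 6.35 came from setting apart both SCAN1#1 libraries (-6.35, the other libraries minus the pair). Setting apart SCAN1#1 replicate 1 and SCAN1#2 replicate 2 gave -5.54 with a camera p of 4.42e-07. In both splits the pair set apart was SCAN1 and had the higher coverage, which is the direction of the real split. These splits therefore do not measure what unrelated labels give. The split by experiment called 192 genes with limma, which points to a structure of the samples by experiment. With experiment as a block the difference was 7.62. The list call was lost with an estimated correlation (adjusted p = 0.559), and the TDP1 genotype and other differences between the lines stay open as untested.

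The share of peak bases at gene ends was higher in each SCAN1 library than in WT of the same experiment. The number of peaks called stays open as a part of it: with lists of equal length the mean within-experiment difference was 1.76 points against 1.68 as deposited, but SCAN1#1 moved from 2.48 to 1.21 in experiment 1 and from 0.54 to 1.61 in experiment 2, and SCAN1#2 from 2.03 to 2.45. Of the 6 arrangements of the libraries within experiments, 2 gave a difference as large in size (1.88 in the real one, -2.12 in another). With equal lists the real one was largest (1.62, next -1.43). The -2.12 and -1.43 came from setting apart SCAN1#1 replicate 1 and SCAN1#2 replicate 2, so there too SCAN1 libraries had the higher share. The difference at gene ends and chance cannot be told apart with so few arrangements. With the summit of each peak counted in place of its bases, the difference of SCAN1#1 in experiment 2 was -0.147. A higher share at gene ends in SCAN1 cells may thus be a property of these few libraries, and the genotype stays untested as its cause.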

How the results depend on the processing

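The alternatives without distal chromosome 14 and those for the p53 and histone means were chosen after the data were seen, as were deposited lists with the block and, for the gene lists, bin medians taken out, a -log10 q of at least 5, the log2 scale, quantile normalization, coverage in 1 library and the block with an estimated correlation. Of 151 values that answer a comparison, 110 stayed within the limits set for a change and 41 did not. Of 382 values for named genes, 379 kept their sign and side of the threshold. These genes were chosen from the same data for differences of the same sign in all comparisons within experiments. None was past the threshold on the percent scale. The choice thus largely set this count, which does not measure robustness. When a library was left out, 8 of the 24 genes moved by over 1.5 times. On the percent scale, 6 did at gene ends only (COL1A1 to -4.55, FOXM1 to -6.41, ZNHIT1 to -6.94, LOXL4 to -8.325, TEAD3 to -8.22 and LAMB3 to 62.2), 2 with a -log10 q of at least 5 (PHLDA2 to 16.04 and OVCA2 to 28.3), 4 with deposited lists and 6 with these and the block. The cause was not tested for any change below unless a smaller number of libraries shows it.

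For regions with a peak in all SCAN1 and no WT library (1673), leaving out 1 library gave 2743 to 9297, experiment 2 alone 15053 and SCAN1#1 alone 4183. For both WT and no SCAN1 library (2466), these gave 3388 to 17667, 18902 and 4217, and a -log10 q of at least 5 gave 1431. Fewer libraries ease both conditions. Counts of genes were 3 higher and 1 lower on the log2 scale (PNRC1, 4.74, adjusted p = 0.0349, and BEX4, -4.70) and 0 elsewhere, and without WT replicate 2 or 1 the difference was -0.597 or 47.9 for ARFRP1, 8.02 or 63.7 for H4C5, 16.9 or 47.1 for COA3, 12.6 or 36.7 for NEURL2, -49.2 or -14.1 for TMEM147, -45.6 or -14.0 for FOXM1, -38.8 or -15.2 for ZNHIT1 and -43.9 or -20.6 for SNAPC5. The block of replicates (experiment) changed no other call than those given here: the genes stayed at 0 and 0, the difference at gene ends was 1.88, and the p53 mean 7.62.

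Leaving out 1 library moved the share at gene ends over -1.02 to 3.04, of gene interiors over -1.82 to 1.88, of other genes over -0.873 to 0.867 and of intergenic sequence over -3.98 to 1.81 points, with the signs turned without WT replicate 2 and without SCAN1#1 replicate 1. Gene interiors were at -0.0965 with equal lists and -0.191 with windows of 2 kb, and other genes at 0.051 with summits.

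Of the lists, 1 was called. None (0) was called with an estimated correlation, with or without the block of replicates, or with gene ends only, 2 (with the histones) with SCAN1#1 alone or with deposited lists and the block, and 1 to 3 when a library was left out, 3 (with histones and olfactory receptors) without WT replicate 1. The p53 mean was 6.92 (adjusted p = 0.559) and 7.62 (0.453) with an estimated correlation and 6.51 (0.189) at gene ends only. In 14 of 15 distinct alternatives with the preset correlation (SCAN1#1 alone is the same fit as leaving out SCAN1#2) the list was called, with adjusted p from 7.8e-07 to 0.00203, and over all 15 the means on the percent scale were 5.04 to 8.17. The histone mean ran from -3.76 without WT replicate 2 over -0.0927 without SCAN1#1 replicate 1 to 12.7 without WT replicate 1, and leaving out 1 library turned the sign of the mean in 10 of the 13 lists.

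The mean log2 ratio of distal chromosome 14 (-2.00) was -2.14 with equal lists. Blocks higher in SCAN1 (17) were 7 with bins of 10 Mb, and lower ones (5) were 9 with equal lists and 3 with bins of 10 Mb. Where leaving out a library left 1 WT library, limma assumed that it varies like the others. The planned windows at transcript starts alone were not run, since strand is not given. How far depth limits the peak lists is not shown by these files.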

Other observations

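In the osteoblast and mesenchymal list, VIM was covered over 30.6% to 48.6% in both genotypes, beside the lower values of COL1A1 and THY1. BGLAP, which encodes osteocalcin, was covered over 83.5% and 75.85% in WT, 92.25% and 100% in SCAN1#1 and 54.3% in SCAN1#2. It was among the 40 genes with the largest differences between the SCAN1 lines. RNASEH2C, which encodes a subunit of the nuclease that cleaves the RNA of hybrids, was covered over 82.0% to 91.0% of its length in all 5 libraries. FOSL1 (84.4% to 100%), JUN (81.2% to 100%) and CCN1 (78.6% to 86.6%) were the immediate early genes with the highest coverage.

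On the distal part of chromosome 14, the peaks called had median fold enrichments of 4.70 in WT and 4.85 in SCAN1#1 in experiment 1, and of 5.31 in WT, 4.68 in SCAN1#1 and 4.95 in SCAN1#2 in experiment 2. Over all other peaks the medians were 4.84 and 4.85, and 5.68, 5.76 and 5.94. With lists of equal length, TEX22 was covered over 21.7% and 13.2% in WT and 6.99% to 15.1% in SCAN1 libraries. CDCA4 was covered over 16.6% and 7.62% in WT and 4.02% to 7.35% in SCAN1 libraries, lower in all 3 comparisons within experiments. Other genes there, such as AHNAK2 and PSMC1, also had peaks in all 3 SCAN1 libraries. BAG5 had no peak in any SCAN1 library in the lists as deposited.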
